A study of Arabidopsis thaliana with 36 samples.

How the data were processed

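The samples were roots and shoots of 2 Arabidopsis thaliana ecotypes, Kas-1 (Kas) and Tsu-1 (Tsu), natural inbred lines of different origin. Plants 24 d old grew in rockwool hydroponics under a 16 h photoperiod at 150 µmol of light, per the labels' protocols. They were moved to medium with 50 µM iron as Fe(III)-EDDHA for 24 h, or kept without iron for 24 h or 48 h. RNA from each sample was biotin-labelled and hybridised to a 1-colour Affymetrix oligonucleotide array, per the labels. The 36 arrays fell into 12 groups of 3, by ecotype, tissue, medium and time as the sample titles give them. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The extraction protocol names rosettes for all samples, while titles name roots and shoots. The tissue of each array was therefore checked with the photosystems and root markers lists.

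The deposited values are log2 expression values, 1 per probe set, as the values themselves show: they ran from 1.31 to 13.47, with array medians from 4.91 to 5.14. The quartiles of the 36 arrays lay close together, from 2.72 to 3.05 for the lower quartile and from 6.68 to 6.83 for the upper, but the sorted values were not identical. The background correction, the summary method, the normalization and the software are not given in the sources used here. No detection calls were used, so a low value is a bright or dim reading, not a statement about presence. The number of arrays limits the precision. No columns were left unmapped, and 0 pairs of arrays held identical values, with a highest correlation between arrays of 0.996.

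Of 22810 probe sets, 64 Affymetrix control probe sets were left out and 22746 were tested, with no filter on dim probe sets. Gene names came from the annotation table of the array, updated through Entrez identifiers to the RefSeq names of assembly TAIR10.1, used for names alone. That table listed 14016 probe sets, of which 13513 named 1 gene and 503 several. The other 8730 are unnamed here. The update matched 13436 of the probe sets with 1 gene and missed 77. These probe sets named 13286 different loci, and 371 of them belonged to loci with more than 1 probe set. Each probe set was tested on its own. Genes without a symbol are given by locus code.

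Expression was compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with 1 mean per group. The 18 arrays of a tissue entered 1 fit, so that its 6 groups shared an estimate of the spread, and tissue by iron was fitted over all 36 arrays. Tests were two-sided, and calls had a Benjamini-Hochberg adjusted p below 0.05 over all 22746 probe sets. Each of 8 iron comparisons set a group without iron against the complete-medium group of its ecotype and tissue. The complete medium was sampled at 24 h alone, so at 48 h the absence of iron and 24 h more growth are not separable. Other contrasts were the ecotype by iron interaction (the change in Kas minus the change in Tsu), Kas minus Tsu on complete medium, 48 h minus 24 h without iron averaged over the ecotypes, and the iron effect in roots minus that in shoots. Counts of calls shared by the ecotypes stand beside the overlap of independent lists of the same sizes. The ecotypes share no array.

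The comparisons, tests, gene lists and rule for named genes were fixed before the data were examined. For each iron comparison the rule took the 8 largest rises and 8 largest falls among calls that named 1 gene and whose 3 arrays without iron all lay on one side of the 3 arrays with iron, plus up to 4 called members of each list. For the other contrasts it took the 5 largest in each direction. Any member of a fixed list may be named with its value.

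The 15 gene lists held 193 members: iron uptake, iron-deficiency regulators, iron chelation and long-distance transport, iron storage, copper uptake, copper proteins, zinc and manganese transport, Fe-S cluster assembly, heme peroxidases, photosystems, chlorophyll synthesis, phosphate starvation, touch and acute stress, circadian clock and root markers. A member was used where its locus code and symbol both matched the reference. This held for 30 members. Another 8 matched by locus alone, and 155 were on no probe set named here, so most textbook iron genes are not analysed here. Iron chelation, iron storage, copper uptake and phosphate starvation kept 0 members. The 5 lists with at least 3 members were tested with camera at its preset correlation of 0.01, adjusted over 40 tests, with an estimated correlation as an alternative.

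The procedure was tested on simulated data drawn from the means of the complete-medium Kas group and the spread of each probe set. In the 24 h comparison of Kas roots it recovered 85% of 100 probe sets changed by 1 on the log2 scale. Of 100 changed by 2 it recovered 100%, with 12 false calls at the unchanged probe sets among the 22746. In the 24 h comparison of Kas shoots the shares were 95% and 99%, with 6 false calls. The simulated noise was independent between probe sets and arrays, so these figures do not cover structure that real arrays share.

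An ecotype index was computed after the values had been seen, because some arrays lay between the ecotypes. It used 33 probe sets higher and 49 lower in Kas than in Tsu, by at least 2 on the log2 scale among the 48 h arrays without iron in both tissues. The index is 0 at the Tsu level and 1 at the Kas level. The 48 h groups lie at 0 and 1 by construction.

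Alternatives planned in advance were quantile normalization, an intensity trend with robust hyperparameters, a filter on dim probe sets, fits on only the groups compared or on all 36 arrays, the replicate number as a block, an estimated correlation for lists, and leaving out each array in turn. Added after seeing the data were leaving out probe sets that differ between ecotypes and the ecotype index as a covariate. Leaving out arrays with an index between 0.15 and 0.85 and taking list members by locus code alone were also added then. A probe set differs here if its adjusted p between Kas and Tsu at 48 h without iron was below 0.05 in roots or shoots. The other 11773 had no called difference, which does not show that the ecotypes are equal there.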

Results

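Expression was measured on 36 arrays in roots and shoots of the Arabidopsis ecotypes Kas and Tsu, in 12 groups of 3, after 24 h with iron or 24 h or 48 h without it. Iron is a cofactor of photosynthesis, respiration and chlorophyll synthesis. Plants short of it raise genes for iron acquisition and signalling. The comparisons ask which genes each ecotype changed without iron, and which of these changes the ecotypes had in common. Marker levels followed the tissue named in the sample titles. The mean of 4 photosystems genes was at least 12.07 in each shoots array and at most 5.37 in each roots array, and the mean of 3 root markers (EXPA7, EXPA18 and PYK10) was at least 7.60 in roots and at most 4.68 in shoots.

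An ecotype index, 0 at the Tsu level and 1 at the Kas level, was set by the 4 groups at 48 h without iron. Of the 8 other groups, 3 lay at the level of their label: 1.01 and 0.990 in Kas shoots with iron and after 24 h without it, and 0.0339 in Tsu shoots with iron. The other 5 held arrays between the ecotypes. In Tsu shoots after 24 h without iron it was 0.674 ± 0.0551 (SD, n = 3). The root groups sampled at 24 h were at 0.290 ± 0.183 in Tsu with iron, 0.641 ± 0.100 in Tsu without iron, 0.752 ± 0.223 in Kas with iron and 0.891 ± 0.269 in Kas without iron (SD, n = 3 each). Of the arrays, 4 in roots and 1 in shoots were closest to an array of another group. Arrays with an index between the ecotypes enter every 24 h comparison in roots and the 24 h comparison in Tsu shoots. They enter the 48 h comparisons in roots through the arrays with iron.

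**Figure D1:**
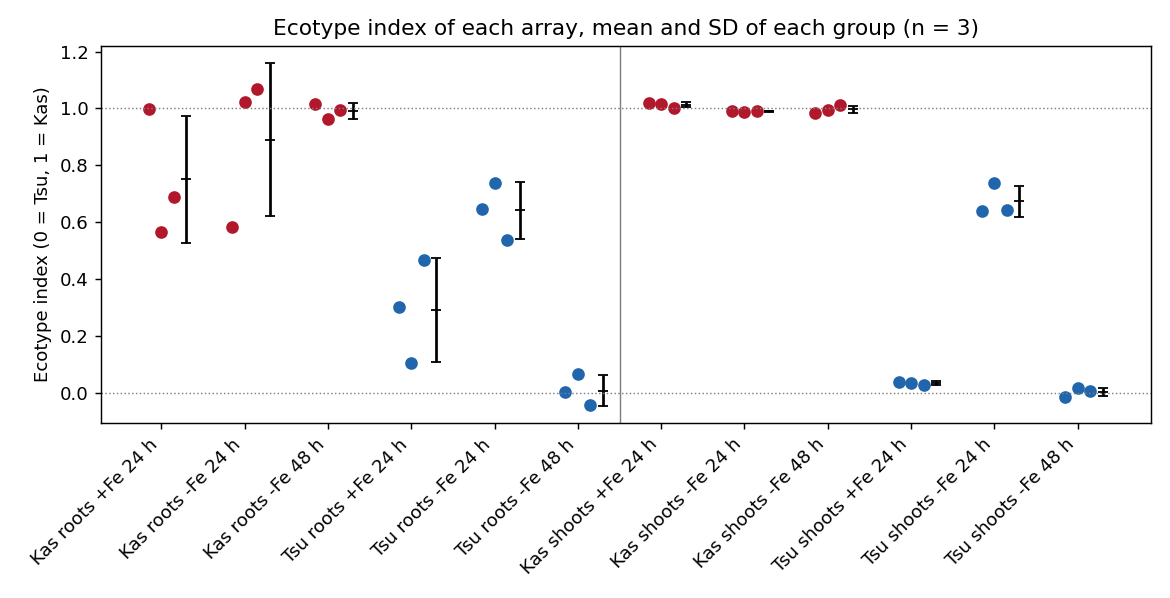
Ecotype index (vertical axis, no unit, 0 for Tsu and 1 for Kas) of each array, with groups along the horizontal axis, roots on the left and shoots on the right. Red points are arrays labelled Kas, blue points arrays labelled Tsu, and black bars the mean and SD of 3 arrays. The 3 arrays of Tsu shoots after 24 h without iron lie between 0.641 and 0.737.

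In Kas roots after 24 h without iron, AT3G07720, a Kelch repeat gene, rose from 6.82 ± 0.32 to 9.05 ± 0.27 (mean log2 ± SD, n = 3), a change of 2.23 (SE 0.28, adjusted p = 0.00329). UGT72E1, a glycosyltransferase of phenylpropanoids, rose by 1.85 (adjusted p = 0.00616), AT3G22570 by 1.32 and AT5G50140 by 1.91. AT3G58060, entered in the fixed list as MTP8, a vacuolar manganese transporter, rose by 1.63 (adjusted p = 0.0341). AT3G42820 (1.59), AT5G37450 (1.53) and AT1G50050 (1.40) rose as well. The deepest falls among named genes were of PRX52, a class III peroxidase, from 6.99 ± 1.36 to 3.35 ± 0.46 (log2 change -3.63, SE 0.50, adjusted p = 0.00419), AT2G15780 (-3.28), AT4G19730 (-2.85) and AT5G52390 (-2.80). AT4G27652 (-2.46), AT5G64120 (-2.42) and AT3G10930 (-2.31) fell, and so did STZ, a zinc-finger stress regulator and the measured member of the touch list, by 2.39 on the log2 scale. Of the heme peroxidases list, the stromal ascorbate peroxidase SAPX fell by 0.82 on the log2 scale, and TAPX had a log2 difference of 0.66 (adjusted p = 0.12).

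The photosystems list fell as a group in Kas roots at 24 h (camera adjusted p = 0.0286, median log2 change -0.65), and lost this call with an estimated correlation (adjusted p = 0.267). None of its members passed the threshold over all probe sets, and 3 of 4 did adjusted over the list alone: the log2 differences were -0.42, -0.88, -0.94 and -0.20. The list's mean level was 5.06 ± 0.45 with iron and 4.45 ± 0.03 without, against array medians of 4.91 to 5.14 over all probe sets. It no longer passed without Kas roots with iron replicate 1 or 3 or without Kas roots at 24 h without iron replicate 1 (adjusted p = 0.124, 0.113 and 0.113). The clock gene GI, with 0 of 1 members called over all probe sets and 1 of 1 adjusted over the list alone, had a log2 difference of 0.86 (adjusted p = 0.0864). None of the 7 measured iron-deficiency regulators and none of the 2 iron uptake genes passed, and adjusted over the list alone 0 and 1 did.

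In all, 442 probe sets passed in Kas roots at 24 h, 142 higher and 300 lower without iron. Of these, 41 rises and 185 falls were at least 2-fold, and 427 had no overlap between the groups, against 18.3% of all probe sets and 10% by chance. Calls are selected on the same arrays, so their lack of overlap adds no support, here and in each other iron comparison. The count rested on single arrays: it was 32, 1567 and 12 without the arrays with iron replicate 1, 2 and 3, and 30 and 42 without the 24 h arrays without iron replicate 2 and 3. The index of the arrays with iron ran from 0.567 to 1.0 and that of the arrays without iron from 0.581 to 1.07. The count was 93 among probe sets that do not differ between ecotypes and 731 with the index as a covariate. It was 22 with only the arrays compared and 1328 with all 36 arrays in 1 fit. Leaving out 1 of those arrays also ended the calls of 13 of the genes named above. Without replicate 3 with iron, the adjusted p became 0.0783 for AT5G50140, 0.168 for AT3G58060, 0.0693 for AT3G42820, 0.112 for AT2G15780, 0.215 for AT4G19730, 0.0975 for AT4G27652, 0.0843 for STZ and 0.168 for AT3G10930. Without replicate 1 with iron, it became 0.138 for AT1G50050, 0.118 for AT5G64120 and 0.119 for SAPX, and without replicate 2 without iron, 0.0698 for AT5G37450 and 0.0723 for AT5G52390. The calls of AT3G07720, UGT72E1, AT3G22570 and PRX52 held without each array in turn.

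After 48 h without iron, Kas roots raised AT3G12900, entered in the fixed list as S8H, the hydroxylase that makes the iron-mobilising coumarin fraxetin, from 3.61 ± 1.28 to 7.08 ± 0.07 (log2 change 3.47, SE 0.56, n = 3, adjusted p = 0.00221). AT1G47400, entered as IMA1, a small peptide of iron-deficiency signalling, rose by 2.63 (adjusted p = 0.0036), AT1G74770, entered as BTSL1, an E3 ligase of the iron response, by 1.48 (adjusted p = 0.011) and AT3G58060 by 1.62 (adjusted p = 0.015). An unnamed probe set rose by 5.88, and the largest rise of a named gene was of AT2G21640, a marker of oxidative and mitochondrial stress, from 3.49 ± 0.25 to 7.27 ± 0.13 (log2 change 3.78, SE 0.53, adjusted p = 0.00102). The transporter gene AT2G04050 rose by 3.49, AT2G41730 by 2.94 and AT5G09570 by 2.83, and the extensin-like cell wall genes AT3G54580, AT5G06630 and AT4G08410 rose by 3.25, 2.93 and 2.81. Falls included AT5G64120 (-3.43), AT4G27652 (-3.30), AT2G22880 (-2.68), CCOAMT (-2.67), PPDK, which makes phosphoenolpyruvate from pyruvate (-3.36, SE 0.63, adjusted p = 0.0053), ASPGB1, an asparaginase (-3.07), AT2G15780 (-2.99) and GAT1_2.1 (-2.74).

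Among the fixed lists at 48 h in Kas roots, the iron uptake gene BGLU42, a beta-glucosidase, rose by 0.70 (adjusted p = 0.0255), and AT3G13610, entered as F6'H1, had a log2 difference of 0.45 (adjusted p = 0.16). Of 7 regulators, ILR3 rose by 0.47 (adjusted p = 0.0234), with 2 called adjusted over the list alone. As a group the regulators had a camera adjusted p of 0.115. STZ fell by 2.52 on the log2 scale (adjusted p = 0.0032), PSAN by 1.36 (1 of 4 photosystems genes over all probe sets, 3 of 4 adjusted over the list alone), SAPX by 0.75 and the copper protein gene ARPN by 0.70. In this comparison 1531 probe sets passed, 645 higher and 886 lower, with 130 rises and 369 falls of at least 2-fold, and 1490 were without overlap between groups (27.8% of all, 10% by chance). The control probe set for 25S ribosomal RNA read 10.2 ± 0.47 with iron and 6.08 ± 0.85 at 48 h (SD, n = 3). The count was 687 and 417 without replicates 1 and 3 with iron, and 945, 864 and 685 without replicates 1, 2 and 3 at 48 h, against 2276 without replicate 2 with iron. With only the arrays compared it was 940, and with all 36 arrays in 1 fit 2908. Leaving out 1 array ended several of the named calls. Without replicate 3 with iron the adjusted p was 0.0906 for BGLU42, 0.193 for ARPN, 0.0656 for PSAN, 0.0677 for AT2G15780 and 0.0677 for GAT1_2.1, without replicate 1 with iron 0.0882 for ILR3 and 0.0587 for SAPX, and without replicate 3 at 48 h 0.122 for AT4G08410.

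Tsu roots after 24 h without iron showed the steepest rises of named genes among the iron comparisons. AT1G10875 rose from 2.32 ± 0.18 to 9.54 ± 0.64 (log2 change 7.22, SE 0.73, n = 3, adjusted p = 6.6e-06). The transporter genes AT2G04050 and AT2G04070, of the multidrug efflux family, rose by 6.89 and 6.0, AT2G41730 by 6.69, the dioxygenase gene AT5G43450 by 6.65, AT2G21640 by 6.62, the glutathione transferase gene GSTU25 by 5.62 (adjusted p = 1.13e-07) and AT3G54520 by 5.23. Falls were led by extensin-like genes, AT3G54580 (-3.09, SE 0.57, adjusted p = 0.00366), AT5G06630 (-2.89), HRGP1 (-2.54), AT4G08410 (-2.51), AT1G23720 (-2.30) and AT2G43150 (-2.22), with AT3G19430 (-2.09) and AT5G44020 (-2.03). Of the iron genes, AT3G13610, entered as F6'H1, which starts the synthesis of coumarins, rose by 1.06 (SE 0.19, adjusted p = 0.00282), AT3G58060 by 1.90 (adjusted p = 0.0052), AT1G47400 by 1.80 (adjusted p = 0.026) and AT1G74770 by 1.24 (adjusted p = 0.026). AT3G12900 had a log2 difference of 1.31 (adjusted p = 0.17) and AT3G07720 of 0.84 (adjusted p = 0.0853).

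None of the 7 regulators passed in Tsu roots at 24 h, 0 adjusted over the list alone, with a camera adjusted p of 0.923. PSAN fell by 1.02 on the log2 scale (1 of 4 photosystems genes, 2 adjusted over the list alone, camera adjusted p = 0.115). Among 1587 probe sets past the threshold, 1120 were higher and 467 lower without iron, 357 and 88 of them by at least 2-fold, and 1570 did not overlap between groups (27.8% of all, 10% by chance). The index was 0.290 ± 0.183 with iron and 0.641 ± 0.100 without, so the arrays without iron lay nearer to Kas. The count fell to 590 among probe sets that do not differ between ecotypes and to 361 with the index as a covariate. With only the arrays compared it was 684, and with all 36 arrays in 1 fit 3221. It was 733 and 2266 without replicates 2 and 3 with iron, 811, 495 and 1036 without replicates 1, 2 and 3 without iron. The adjusted p without replicate 2 with iron became 0.234 for AT4G08410, 0.0941 for AT1G23720 and 0.13 for AT2G43150, and without replicate 2 without iron 0.0765 for AT5G44020 and 0.158 for PSAN.

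At 48 h without iron, Tsu roots raised regulators and other genes of the iron response. BHLH101, a transcription factor of the iron-deficiency response, rose from 2.81 ± 0.27 to 6.30 ± 1.57 (log2 change 3.49, SE 0.48, n = 3, adjusted p = 0.00122). AT3G07720 rose by 3.49 (SE 0.28, adjusted p = 3.51e-06), AT3G61930 by 3.31, AT3G12900 by 3.28 (adjusted p = 0.00704), the transporter gene AT4G34950 by 2.98 (adjusted p = 2.25e-05), AT1G47400 by 2.84 (adjusted p = 0.0049), AT3G58060 by 2.31 (adjusted p = 0.0046), AT1G74770 by 1.88 (adjusted p = 0.0069), AT3G13610 by 1.11 (adjusted p = 0.00694) and AT1G18910, entered as BTSL2, by 0.77 (adjusted p = 0.0086). PYE, a transcription factor that tunes the iron response, rose by 0.89 (adjusted p = 0.0352). AT3G29970 rose by 5.64 with uneven replicates (8.5 ± 3.68 against 2.86 ± 0.54), AT5G66985 by 3.05 and AT3G10040 by 2.97. The falls were AT5G45500 (-4.44), AT3G29410 (-3.93), AT4G07820 (-2.89), ZW9 (-2.41), AT3G11370 (-2.22) and the extensin-like AT3G54580 (-2.88), AT5G06630 (-2.49) and HRGP1 (-2.33).

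Of 7 regulators, 2 passed in Tsu roots at 48 h, over all probe sets and adjusted over the list alone (camera adjusted p = 0.115). The zinc transporter ZIP9 had a log2 difference of 1.20 (adjusted p = 0.074, 0 of 1 called over all probe sets and 1 of 1 adjusted over the list alone). In total 368 probe sets passed, 224 higher and 144 lower, 117 and 79 by at least 2-fold, with 343 of them without overlap (17.2% of all, 10% by chance). The count was 55 without replicate 1 at 48 h and at most 461 without any other array, and the direction turned without replicate 2 with iron (117 higher, 168 lower) and without replicate 2 at 48 h (210 higher, 251 lower). Without replicate 3 at 48 h it was 325 higher and 75 lower. The index was 0.290 with iron and 0.00754 at 48 h, and AT5G45500, which fell, was far above Tsu in Kas shoots. The count was 15 with only the arrays compared, all of them rises, so no fall named above passed there. With all 36 arrays in 1 fit it was 1349. Without replicate 1 at 48 h the adjusted p became 0.214 for AT3G29970, 0.0619 for AT3G12900, 0.133 for AT5G66985, 0.192 for AT3G10040, 0.212 for PYE, 0.0632 for AT3G13610, 0.0569 for AT3G29410, 0.0602 for AT4G07820, 0.135 for AT3G54580, 0.159 for AT5G06630, 0.143 for ZW9, 0.18 for HRGP1 and 0.102 for AT3G11370. BHLH101, AT3G07720, AT3G61930, AT4G34950 and AT5G45500 passed without each array in turn.

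**Figure D2:**
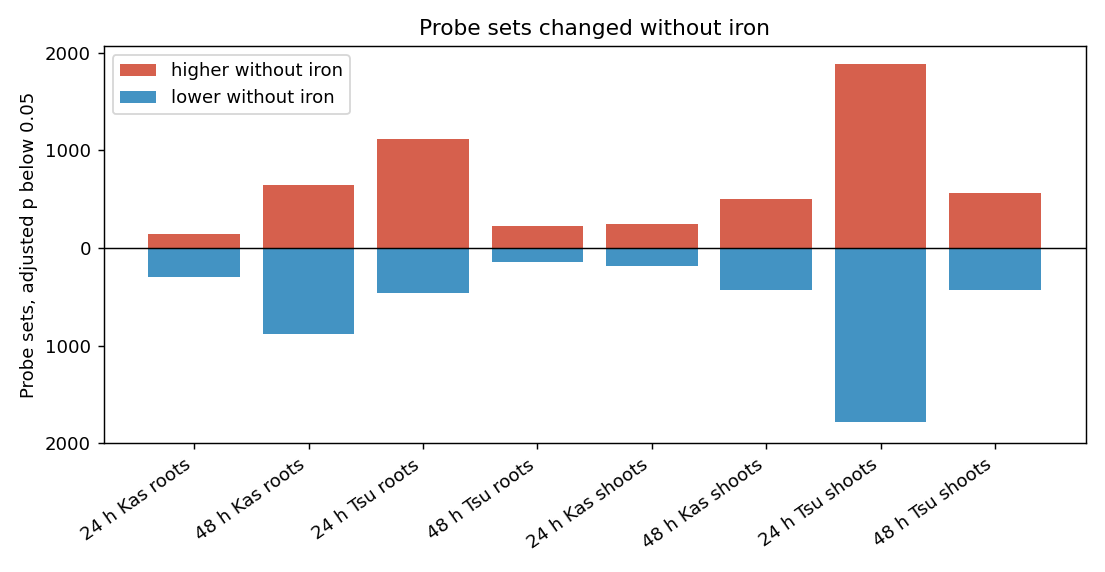
Number of probe sets with an adjusted p below 0.05 (vertical axis) in each of the 8 iron comparisons (horizontal axis). Red bars above 0 count probe sets higher without iron, blue bars below 0 those lower without it, with 1886 and 1780 in Tsu shoots at 24 h and 142 and 300 in Kas roots at 24 h.

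Kas shoots after 24 h without iron raised AT1G47400, the IMA1 peptide gene, from 4.14 ± 0.82 to 6.65 ± 0.12 (log2 change 2.51, SE 0.30, n = 3, adjusted p = 0.000165). AT3G28270 rose by 1.72, AT5G05250 by 1.41, AT5G60250 by 1.39, AT5G62130 by 1.38, AT1G75960 by 1.37, AT1G20120 by 1.33 and AT1G52000 by 1.27. AT3G13610, entered as F6'H1, rose by 1.26 (adjusted p = 0.021), and CCS, the copper chaperone of copper/zinc superoxide dismutase, by 0.91 (adjusted p = 0.00232). Falls included the osmotin gene OSM34 (-2.08), AT1G30700 (-1.70), AT5G52390 (-1.58), the amylase gene AMY1 (-1.52, SE 0.15, adjusted p = 2.64e-05), JRG21 (-1.36), AT2G28710 (-1.17), WES1, an auxin-conjugating enzyme (-1.15), and the defensin gene PDF1.4 (-1.15). None of the 7 regulators passed, 0 adjusted over the list alone (camera adjusted p = 0.528). BHLH101 had a log2 difference of 0.62 and PYE of 0.43.

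This comparison called 424 probe sets, 241 higher and 183 lower, 53 and 22 by at least 2-fold, and 423 of them did not overlap between groups (21.0% of all, 10% by chance). Without replicates 2 and 3 with iron the count was 233 and 215, and without replicates 1, 2 and 3 without iron 225, 161 and 163. It was 34 among probe sets that do not differ between ecotypes and 235 with all 36 arrays in 1 fit. The adjusted p became 0.112 for OSM34 without replicate 2 with iron, 0.155 for PDF1.4 without replicate 3 without iron and 0.107 for AT3G13610 without replicate 1 with iron.

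At 48 h in Kas shoots the same peptide gene AT1G47400 was higher by 3.58 (7.71 ± 0.16 against 4.14 ± 0.82, SE 0.30, n = 3, adjusted p = 1.87e-06). AT5G05250 rose by 2.48, BUB3.2, a homolog of spindle checkpoint genes, by 1.93, AT5G60250 by 1.67, AT3G13610 by 1.43, AT1G69400 by 1.39, the defensin gene PDF1.2 by 1.28 and SAG29 by 1.25. PYE rose by 1.18 (adjusted p = 7.21e-05) and CCS by 0.80 (adjusted p = 0.00385), while BHLH101 had a log2 difference of 1.36 (adjusted p = 0.06). The lipid transfer gene AT4G22490 fell by 1.56 on the log2 scale, AT1G62500 by 1.21, AT1G10640 by 1.07, AT1G14890 by 0.98, the cold-regulated COR27 by 0.95, AT1G73040 by 0.94, and AT4G23680 and AT5G56910 by 0.90 each. Of the regulators 1 of 7 passed, 2 adjusted over the list alone (camera adjusted p = 0.115).

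Calls at 48 h in Kas shoots numbered 935, of which 501 were higher and 434 lower, 88 and 11 by at least 2-fold, and 925 had no overlap (23.1% of all, 10% by chance). Without dim probe sets 529 were higher and 595 lower. The count was 596 and 466 without replicates 1 and 3 with iron, and 473 and 452 without replicates 1 and 2 at 48 h. With all 36 arrays in 1 fit it was 585. Without replicate 1 at 48 h the adjusted p became 0.0963 for SAG29, 0.15 for AT4G23680 and 0.0958 for AT5G56910, and without replicate 3 at 48 h 0.164 for AT1G62500.

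Tsu shoots after 24 h without iron raised CCS by 1.71 (9.07 ± 0.16 against 7.35 ± 0.05, SE 0.15, n = 3, adjusted p = 8.16e-08), AT1G47400 by 2.71 (adjusted p = 2.2e-06), AT5G05250 by 2.53, BHLH101 by 3.13 (SE 0.40, adjusted p = 1.06e-05), PYE by 1.07 (adjusted p = 1.84e-05) and AT1G18910, entered as BTSL2, by 0.96 (adjusted p = 5.9e-05). The 8 largest rises of named genes were others, and an unnamed probe set rose by 7.65: AT4G29200 (5.25), AT5G59670 (4.88), AT1G73490 (4.78), AT2G15560 (4.73), AT5G45500 (4.43), ZW9 (4.35), AT3G44070 (3.97) and the chitinase gene CHI (3.90). The falls were the expansin-like EXLA1 (-2.43), AT5G15780 (-2.33), the auxin response gene IAA29 (-2.13), AT1G13650 (-2.07), AT3G60980 (-2.05), AT3G16750 (-2.03), the tubulin gene TUA6 (-1.97) and AT3G62950 (-1.94). The index of these 3 arrays was 0.674 ± 0.0551, against 0.0339 with iron. On complete medium, AT4G29200, AT5G59670, AT1G73490, AT5G45500 and CHI were also the 5 named genes most above Tsu in Kas shoots, and TUA6 was among the 5 most below.

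Several fixed lists held called members in Tsu shoots at 24 h. Chlorophyll synthesis had 2 falls, HEMB1 (-1.07, adjusted p = 7e-05) and CHLM (-0.41), and 1 rise, GSA1 (0.55), among 4 genes (3 adjusted over the list alone, camera adjusted p = 0.528). Both heme peroxidases fell, SAPX by 0.62 and TAPX by 0.38 on the log2 scale. The plastid cysteine desulfurase CPNIFS, which supplies sulfur to Fe-S clusters, fell by 0.51, as 1 of 3 Fe-S genes (2 adjusted over the list alone, camera adjusted p = 0.397). BGLU42 rose by 0.46 and STZ by 1.22. In total 3666 probe sets passed, 1886 higher and 1780 lower (1838 and 1887 after quantile normalization), 388 and 218 by at least 2-fold, and 3578 did not overlap between groups (32.2% of all, 10% by chance). Of these calls 940 (25.6%) lay at probe sets without a called ecotype difference, a class that holds 51.8% of all tested probe sets. When adjusted over such probe sets alone, 584 passed. Calls ended for BGLU42 without replicate 2 with iron (adjusted p = 0.0953), for TAPX without replicate 3 with iron (0.168) and for CHLM without replicate 2 without iron (0.0524).

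At 48 h in Tsu shoots, AT1G47400 was higher by 2.34 (7.78 ± 0.07 against 5.44 ± 0.54, SE 0.30, n = 3, adjusted p = 0.000162), AT5G05250 by 2.15, BHLH101 by 1.90 (adjusted p = 0.00918), CCS by 1.57 (adjusted p = 5.21e-06) and PYE by 1.16 (adjusted p = 8.63e-05). SUFE2, which activates sulfur transfer for Fe-S clusters, rose by 1.5, AT1G80130 by 1.62, AT4G14090 by 1.59 and CHI by 1.5. Of the copper proteins both passed, with ARPN, a plantacyanin, up by 0.53 (adjusted p = 0.0289). EXLA1 (-1.51), AT5G15780 (-2.12), AT3G06070 (-1.41), BZIP61 (-1.38), AT4G18670 (-1.33), AT5G01015 (-1.29), AT5G12050 (-1.22) and AT3G05730 (-1.20) fell. TAPX fell by 0.53 and CHLM by 0.40 on the log2 scale, STZ rose by 0.77, and 2 of 7 regulators passed, 2 adjusted over the list alone (camera adjusted p = 0.175). The chlorophyll list had a median of -0.25 (camera adjusted p = 0.115).

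For this comparison 988 probe sets passed, 558 higher and 430 lower, 88 and 38 by at least 2-fold, and 924 were without overlap (18% of all, 10% by chance). The count was 532, 610 and 479 without replicates 1, 2 and 3 with iron, and 360, 427 and 1993 without replicates 1, 2 and 3 at 48 h. With only the arrays compared it was 165, and with all 36 arrays in 1 fit 535. Replicate 3 at 48 h was closest to an array with iron, and its 25S control read 9.07, against 5.84 and 6.67 in replicates 1 and 2. The adjusted p became 0.132 for AT5G15780 without replicate 1 with iron, 0.109 for ARPN and 0.0856 for TAPX without replicate 3 with iron, and 0.146 for CHLM without replicate 1 at 48 h.

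Some responses appeared in both ecotypes. Genes of this and the next paragraph that no rule or fixed list names, and AT5G05250 wherever it falls outside the rule, were chosen after their values were seen and were not refitted without single arrays. In roots at 48 h, AT3G12900 (3.47 in Kas and 3.28 in Tsu), AT3G07720 (2.28 and 3.49), AT3G61930 (2.76 and 3.31), AT1G47400 (2.63 and 2.84), AT5G38820 (1.79 and 2.85), UGT72E1 (1.92 and 1.74) and AT3G58060 (1.62 and 2.31) rose in each. Of the 4 probe sets that fell in both, 2 have a gene name, chosen here after their values were seen: AT3G53820 (-1.82 and -0.76) and AT1G62660 (-0.45 and -0.50). In all 27 were shared, 23 up against 6.35 expected of independent lists and 4 down against 5.61, and 44 changed in opposite directions against 12.8. Without replicate 1 of Tsu roots at 48 h, 15 were shared. The number was 7 with only the arrays compared and 78 with all 36 arrays in 1 fit. At 24 h in roots 25 were shared (17 up against 6.99, 8 down against 6.16), among them AT3G58060, UGT72E1 and AT3G42820, and 51 went in opposite directions against 17.7. The 24 h count was 13 without Tsu roots without iron replicate 2, 4, 41 and 3 without Kas roots with iron replicates 1, 2 and 3, and 3 and 5 without Kas roots without iron replicates 2 and 3. It was 2 with only the arrays compared, 131 with all 36 arrays in 1 fit and 7 among probe sets that do not differ between ecotypes. The index in roots rose at 24 h from 0.752 to 0.891 in Kas and from 0.290 to 0.641 in Tsu. At 48 h it was 0.991 in Kas and 0.00754 in Tsu. The expectation of independent lists does not cover these shifts.

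In shoots at 48 h, the shared rises included AT1G47400 (3.58 in Kas and 2.34 in Tsu), AT5G05250 (2.48 and 2.15), PYE (1.18 and 1.16), CCS (0.80 and 1.57) and PPDK (0.86 and 0.81). AT3G19850 (-0.83 and -0.53) and AT1G32090 (-0.61 and -0.62) fell in both. There were 65 shared calls, 51 up against 12.3 expected and 14 down against 8.20, with 38 opposite against 20.1. This count was 38 and 43 without Tsu shoots with iron replicates 1 and 3, 32 and 40 without Tsu shoots at 48 h replicates 1 and 2, 41 and 38 without Kas shoots with iron replicates 1 and 3, and 41 without Kas shoots at 48 h replicate 1 or 2. It was 25 with only the arrays compared, 31 with all 36 arrays in 1 fit and 107 without dim probe sets. At 24 h in shoots, AT1G47400 (2.51 and 2.71), AT5G05250 (1.41 and 2.53), CCS (0.91 and 1.71) and BUB3.2 (1.27 and 0.79) rose in both, and an unnamed probe set fell in both (-5.09 and -3.19). There were 60 shared calls, 42 up against 20 expected and 18 down against 14.3, and 115 opposite against 34.0. The Tsu arrays without iron had an index of 0.674, which the expectation of independent lists does not cover, and 3 shared calls were left among probe sets that do not differ between ecotypes. That count was 37 and 36 without Kas shoots with iron replicates 2 and 3, and 33, 24 and 26 without Kas shoots without iron replicates 1, 2 and 3. With all 36 arrays in 1 fit it was 31.

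**Figure D3:**
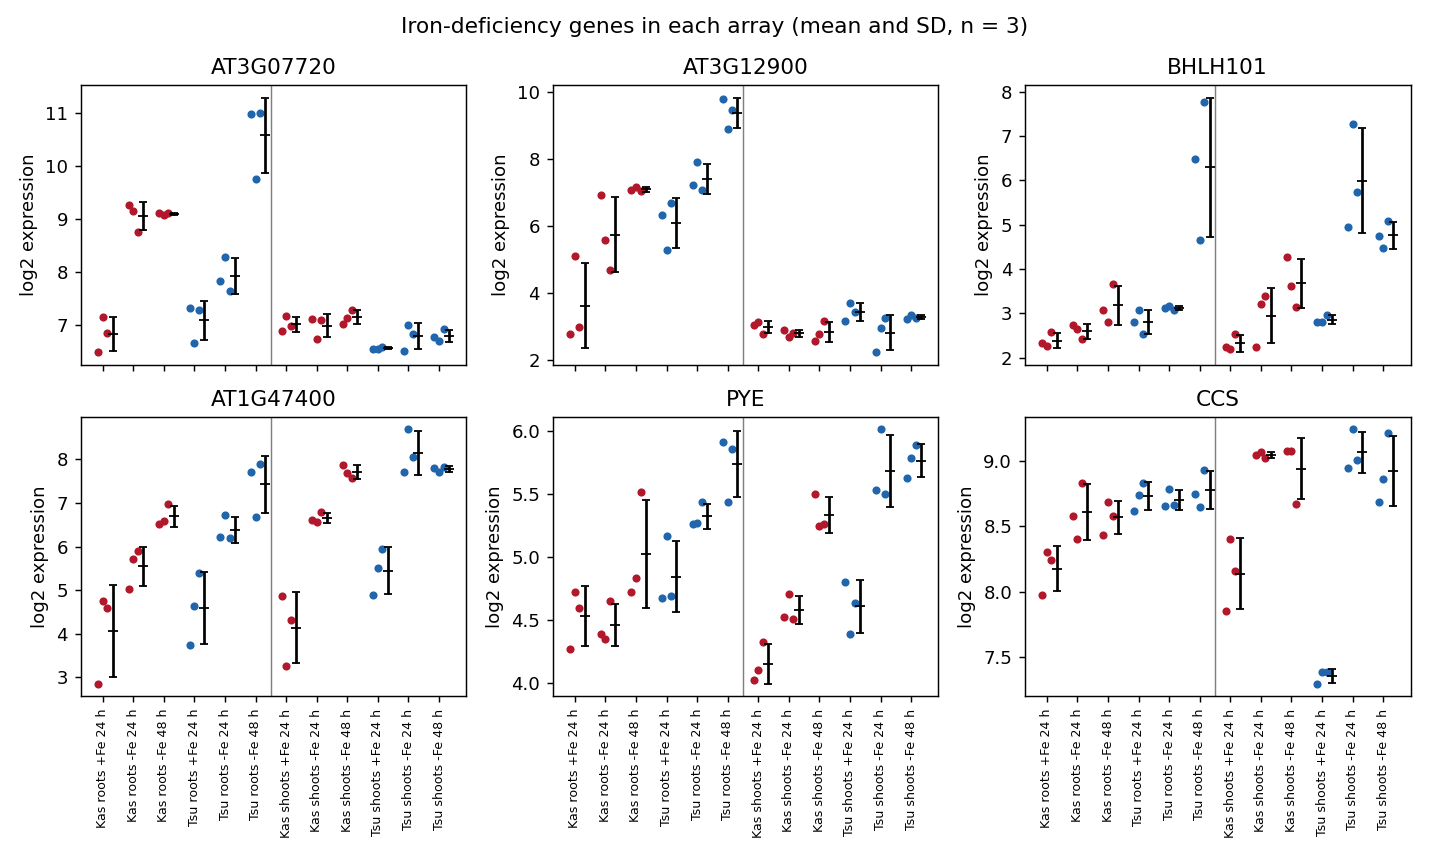
Log2 expression (vertical axes) of AT3G07720, AT3G12900, BHLH101, AT1G47400, PYE and CCS in each array, with the 12 groups along the horizontal axis, roots left of the grey line and shoots right of it. Red points are Kas arrays, blue points Tsu arrays, and black bars the mean and SD of 3 arrays. AT3G12900 rose at 48 h in roots of both ecotypes, and AT1G47400 and CCS were higher without iron in shoots of both.

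The other fixed lists showed few calls. Of the heme peroxidases, SAPX alone passed in Kas roots at 24 h and 48 h, with 2 and 1 called adjusted over the list alone. Of the 2 copper proteins, ARPN passed in Kas roots at 48 h (2 adjusted over the list alone) and CCS in every shoots comparison (1, 1, 1 and 2 adjusted over the list alone in Kas at 24 h and 48 h and Tsu at 24 h and 48 h). Among the 3 root markers 0 passed in any iron comparison, with 2 adjusted over the list alone in Tsu roots at 24 h, 1 each in Tsu roots at 48 h, Kas shoots at 24 h and Tsu shoots at 48 h, and a lowest camera adjusted p of 0.397. No gene of the photosystems list passed in shoots. The lists for iron chelation, iron storage, copper uptake and phosphate starvation had 0 measured members. Of 40 camera tests over 5 lists, 1 passed, and 0 did with an estimated correlation. None passed with only the arrays compared or without dim probe sets, and 9 of 48 did with members taken by locus code alone, 2 of them with an estimated correlation.

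The ecotypes, as labelled, differed in the iron response of several genes by the interaction test. In roots at 24 h AT3G54580 (4.22, SE 0.81, adjusted p = 0.00627), AT5G06630 (4.03), HRGP1 (3.49), AT2G43150 (3.29) and AT1G23720 (3.09), all extensin-like, changed more upward in Kas. AT1G10875 (-7.44, SE 1.03, adjusted p = 0.000353), AT2G41730 (-7.01), AT2G04050 (-6.97), AT5G43450 (-6.74) and AT2G21640 (-6.39) changed more upward in Tsu. In total 1146 probe sets passed, 352 positive and 794 negative. Arrays of both labels lay between the ecotypes: the mean index with and without iron was 0.752 and 0.891 in Kas, and 0.290 and 0.641 in Tsu. The contrast is therefore not one of Kas against Tsu alone. In this contrast 1146 is the number of calls over all probe sets. The count was 700 and 558 without Tsu roots without iron replicates 1 and 2, 532, 2493 and 530 without Kas roots with iron replicates 1, 2 and 3, and 676 and 714 without Kas roots without iron replicates 2 and 3. It was 452 among probe sets that do not differ between ecotypes and 2615 with all 36 arrays in 1 fit. The adjusted p became 0.0679 for AT2G43150 without Kas roots without iron replicate 3 and 0.0752 for AT1G23720 without Kas roots with iron replicate 1.

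In roots at 48 h AT3G54580 (6.13, adjusted p = 0.00102), AT5G06630 (5.42), AT4G08410 (5.41), AT3G29410 (5.19) and AT5G45500 (5.06) had the most positive interactions among named genes, and PPDK (-4.50, adjusted p = 0.00784), AT4G33550 (-4.36), ASPGB1 (-4.29), AT5G64120 (-4.29) and AT4G27652 (-3.90) the most negative. BHLH101 changed more upward in Tsu (-2.70, adjusted p = 0.024), as did AT5G05250 (-2.43, adjusted p = 0.00187) and ARPN (-1.08, adjusted p = 0.0226). The arrays with iron had a mean index of 0.752 in Kas and 0.290 in Tsu. A total of 1805 passed, 757 positive and 1048 negative, and after quantile normalization 847 were positive and 828 negative. It was 767 without Tsu roots at 48 h replicate 1, 757 without Kas roots with iron replicate 3 and 993 without Kas roots at 48 h replicate 3. It was 992 with the index as a covariate, 1006 with only the arrays compared and 3656 with all 36 arrays in 1 fit.

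In shoots at 24 h the interaction was positive for EXLA1 (3.13, SE 0.34, adjusted p = 3.41e-06), AT5G15780 (2.78), AT5G48490 (2.44), AT1G13650 (2.44) and AT2G01870 (2.42), and negative for AT4G29200 (-5.29), AT5G59670 (-5.09), AT1G73490 (-4.89), AT2G15560 (-4.79) and AT5G45500 (-4.29). BHLH101 (-2.51, adjusted p = 0.0054) and CCS (-0.80, adjusted p = 0.0168) were more upward in Tsu, as was GI (-0.44, adjusted p = 0.0399). Of 2556 calls, 1154 were positive and 1402 negative. The Tsu arrays without iron had the index of 0.674 given above. Among probe sets that do not differ between ecotypes 376 passed. The adjusted p of AT5G15780 became 0.0565 without Tsu shoots with iron replicate 1.

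At 48 h in shoots EXLA1 (2.29, adjusted p = 0.00113), AT5G48490 (2.18), AT1G06830 (2.06), AT5G01015 (2.02) and AT1G76240 (1.88) were positive, and AT1G80130 (-2.48, adjusted p = 0.00113), AT1G73040 (-1.86), AT4G22490 (-1.80), AT4G14090 (-1.78) and SUFE2 (-1.68) negative. CCS was more upward in Tsu (-0.77, adjusted p = 0.046). There were 897 calls, 443 positive and 454 negative (505 and 401 after quantile normalization), a near-even split whose majority also turned without most single arrays. The count was 565 without Tsu shoots with iron replicate 3, 533 and 1577 without Tsu shoots at 48 h replicates 1 and 3, 570 without Kas shoots with iron replicate 3, and 539 and 505 without Kas shoots at 48 h replicates 1 and 2. It was 479 with only the arrays compared and 468 with all 36 arrays in 1 fit.

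On complete medium, the named gene that differed most between shoots of the ecotypes was AOP3, a glucosinolate side-chain enzyme, at 3.15 ± 0.21 in Kas and 10.02 ± 0.13 in Tsu (log2 difference -6.87, SE 0.14, n = 3, adjusted p = 4.55e-18). AT3G22240 (-6.20), TUA6 (-5.44), the immune receptor gene CSA1 (-5.24) and AT3G47250 (-5.11) were lower in Kas, and CHI (5.73, 9.12 ± 0.18 against 3.40 ± 0.30), AT4G29200 (5.51), AT1G73490 (4.94), AT5G45500 (4.67) and AT5G59670 (4.47) higher. CCS was higher in Kas by 0.78 and ARPN lower (-1.87). Here 7549 probe sets passed, 2997 higher and 4552 lower in Kas. Probes were designed on another ecotype, so differences of sequence enter this contrast, and the 25S control read 9.03 ± 0.46 in Kas and 5.55 ± 0.37 in Tsu (SD, n = 3).

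In roots on complete medium AT4G09890 (2.55, SE 0.31, adjusted p = 0.000255), AT2G15780 (2.30), ASPGB1 (2.09), AT3G61490 (1.90) and MGL, a methionine-degrading enzyme (1.84), were higher in Kas. AT3G62400 (-3.16, adjusted p = 1.66e-06), AT3G54580 (-2.84), AT4G10550 (-2.49), AT3G12900 (-2.48) and AT2G43150 (-2.47) were lower, and so was ARPN (-1.61, adjusted p = 0.000192). The 2243 calls split into 778 higher and 1465 lower in Kas, 34.7% higher, and after quantile normalization 54.8% were higher. The count was 1033 without Tsu replicate 2 and 460, 3748 and 608 without Kas replicates 1, 2 and 3, and index values here were 0.752 in Kas and 0.290 in Tsu. It was 14 with only the arrays compared and 1178 without dim probe sets. With all 36 arrays in 1 fit it was 4289. The adjusted p became 0.174 for AT2G15780, 0.189 for ASPGB1, 0.103 for MGL and 0.0839 for AT3G12900 without Kas replicate 1, and 0.0618 for AT2G43150 without Kas replicate 3.

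From 24 h to 48 h without iron, averaged over the ecotypes, roots raised AT3G61930 (2.0, SE 0.32, adjusted p = 0.00283), BHLH101 (1.88, adjusted p = 0.00583), AT3G12900 (1.66), AT3G19430 (1.41) and AT3G07720 (1.35, adjusted p = 0.00157). AT5G59680 (-2.45), AT4G29200 (-2.32), AT5G45500 (-2.16), AT3G29410 (-2.12) and AT3G46270 (-1.92) fell. Of 644 calls, 186 were higher and 458 lower, and 145 passed with the index as a covariate. The index of Tsu roots was 0.641 at 24 h and 0.00754 at 48 h. The count was 380 and 334 without Tsu 24 h replicates 1 and 2, 413 without Tsu 48 h replicate 1, 290 without Kas 24 h replicate 2, and 389 and 383 without Kas 48 h replicates 2 and 3. With only the arrays compared it was 1426, and with all 36 arrays in 1 fit 1574. Without Kas 24 h replicate 2 the adjusted p became 0.0843 for AT3G12900, 0.0677 for AT4G29200, 0.0713 for AT5G45500 and 0.0593 for AT3G29410.

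In shoots, AT5G03350 (1.10), AT1G69730 (1.04), AT2G29170 (1.02), AT3G09960 (1.02, SE 0.08, adjusted p = 5.98e-08) and AT3G60980 (1.02) rose from 24 h to 48 h. AT4G29200 (-2.48), AT1G73490 (-2.43), AT5G45500 (-2.40), AT2G15560 (-2.37) and ZW9 (-2.19) fell, and all 5 were also among the 8 largest rises of named genes in Tsu shoots at 24 h. Calls numbered 1168, 625 higher and 543 lower (466 and 502 without dim probe sets). With all 36 arrays in 1 fit 637 passed, 303 higher and 334 lower. The index of Tsu shoots was 0.674 at 24 h and 0.00224 at 48 h.

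Roots and shoots differed in the iron effect averaged over ecotypes and times. AT3G12900 (2.81, SE 0.38, adjusted p = 2.24e-05), AT3G58060 (1.77, adjusted p = 4e-05), AT1G10875 (2.62), AT2G04050 (2.58), AT5G10040 (2.95) and AT3G29970 (2.89) changed more upward in roots. AT2G15780 (-2.19), PRX52 (-2.18), PPDK (-1.95), AT5G45500 (-1.92) and the glutaredoxin GRX480 (-1.78) changed more downward there, and CCS more upward in shoots (-1.04, adjusted p = 3e-06). A total of 1344 probe sets passed, 666 positive and 678 negative, near even, and 868 without Kas roots with iron replicate 3. The adjusted p became 0.0514 for AT5G10040 without that array and 0.0565 for AT3G29970 without Tsu shoots with iron replicate 3.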

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

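The tests of explanations and the schemes of splits in this part, with the count of uneven splits, were chosen after the results were seen, and the splits of the iron labels within each ecotype were added only once the splits across ecotypes had been counted. The genes below were picked out because the iron effect differed between ecotypes as labelled, or between tissues, by a test of the difference itself.

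In roots at 24 h, the named genes with the most positive differences were extensin-like. The change in Kas minus the change in Tsu was 4.22 for AT3G54580, 4.03 for AT5G06630, 3.49 for HRGP1, 3.29 for AT2G43150 and 3.09 for AT1G23720. It was -7.44 for AT1G10875, -7.01 for AT2G41730, -6.97 for the transporter gene AT2G04050, -6.74 for the dioxygenase gene AT5G43450 and -6.39 for AT2G21640, a marker of mitochondrial stress, among 1146 probe sets past the threshold. At 48 h the extensin-like genes AT3G54580 (6.13), AT5G06630 (5.42) and AT4G08410 (5.41) were again positive, with AT3G29410 (5.19) and AT5G45500 (5.06). PPDK, which makes phosphoenolpyruvate, was at -4.50, AT4G33550 at -4.36, the asparaginase gene ASPGB1 and AT5G64120 at -4.29 each and AT4G27652 at -3.90, among 1805. Of 100 splits exchanging ecotype labels, 3 gave as many calls at 24 h (highest other 1918) and 8 at 48 h (highest other 4161). Beside the real split, 1 of the 2 at 24 h and 5 of the 7 at 48 h placed Kas arrays unevenly between the media, by at least 2. All of them were uneven by at least 1, and splits uneven by less than 2 reached 1918 calls at 24 h and 2005 at 48 h. Counts above the real one point to a structure of the samples: an uneven split carries part of the ecotype difference by construction. Whether that gave these counts in roots was not tested, so chance at 48 h stays open by this scheme. Of 100 splits of the iron labels within each ecotype, 2 did at 24 h (highest other 1193) and 1 at 48 h (highest other 467). These low shares argue against an arbitrary assignment of the iron labels within the ecotypes. The other splits break up the iron groups of each ecotype (median of the other counts 0). This added scheme therefore does not decide whether the difference between ecotypes arose by chance.

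In shoots, the expansin-like gene EXLA1 had the most positive difference of the named genes at both times. At 24 h it was 3.13 for EXLA1, 2.78 for AT5G15780, 2.44 for AT5G48490, 2.44 for AT1G13650 and 2.42 for AT2G01870, and -5.29 for AT4G29200, -5.09 for AT5G59670, -4.89 for AT1G73490, -4.79 for AT2G15560 and -4.29 for AT5G45500, among 2556. At 48 h EXLA1 (2.29), AT5G48490 (2.18), AT1G06830 (2.06), AT5G01015 (2.02) and AT1G76240 (1.88) changed more upward in Kas, and AT1G80130 (-2.48), AT1G73040 (-1.86), AT4G22490 (-1.80), AT4G14090 (-1.78) and SUFE2 of Fe-S assembly (-1.68) more upward in Tsu, among 897. Splits exchanging ecotype labels gave as many calls in 7 of 100 at 24 h (highest other 8938) and 10 of 100 at 48 h (highest other 10668), and the 6 and 9 of them beside the real split all placed Kas arrays unevenly, by at least 2. The scheme therefore reads the ecotype difference and does not decide on chance. Splits of the iron labels within each ecotype did in 1 (highest other 2138) and 2 (highest other 998). As in roots, this argues against an arbitrary assignment of the iron labels, but does not decide on chance for the difference between ecotypes.

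Between roots and shoots, the iron effect differed for AT5G10040 (2.95), AT3G29970 (2.89), the fraxetin gene AT3G12900 (2.81), AT1G10875 (2.62) and AT2G04050 (2.58), all more upward in roots, and for AT2G15780 (-2.19), the peroxidase gene PRX52 (-2.18), PPDK (-1.95), AT5G45500 (-1.92) and the glutaredoxin gene GRX480 (-1.78). In all 1344 passed, and of 100 splits only the real one, 1, gave as many (highest other 37). These splits reassigned media and times within each ecotype and tissue. They argue against an arbitrary assignment of those labels, but do not isolate the difference between tissues.

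The first pattern weighed is the set of 3666 calls in Tsu shoots at 24 h, which include AT4G29200 and CHI, genes that Kas shoots express at high levels. Of these calls 83.7% had the sign of Kas minus Tsu (69.3% for the calls of Kas shoots at 24 h), so Kas material in these arrays is a candidate explanation. The change that a mixture of the ecotypes would give correlated with the observed change at 0.895 over the calls. Both changes subtract the same Tsu arrays with iron, and the mixing share is the index of the arrays tested. This raises the correlation by construction, and no comparison value was computed. The highest index, 0.737, argues against Kas arrays under a Tsu label. At most 45.1% of the diagnostic probe sets lay near either ecotype's level, against at least 68.3% in arrays without an intermediate index, which argues against a recombinant inbred line, while a first-generation hybrid was not excluded. An iron response stays open for the calls as a set. Among the 3666 calls, 940 lie at probe sets without an ecotype difference. Of these, 9.47% lay beyond all 15 other shoots arrays (1.16% of all tested probe sets). Calls were selected for a change in these arrays, so no chance rate applies. For BHLH101, AT1G47400 and PYE, the 3 arrays all lay above Tsu shoots with iron and Kas shoots at 24 h without iron. BHLH101 and AT1G47400 were at least 4.96 and 7.71, against at most 2.97 and 5.95 in Tsu and 3.38 and 6.78 in Kas. For these genes this argues against a mixture of those groups. CCS did not exceed Kas in each array (lowest 8.95, highest in Kas 9.07). Kas shoots at 48 h overlapped the 3 arrays for AT1G47400 and PYE.

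The second pattern is the intermediate index in root arrays, where genes such as AT3G62400 that separate the ecotypes had middle levels. By the probe sets high in Kas and by those low in Kas the same 8 arrays were intermediate, so Kas and Tsu material in 1 array is a candidate explanation. The share of diagnostic probe sets near either ecotype's level ran from 11% to 37.8% in 7 of the 8 arrays, which argues against a recombinant inbred line there. It was 61.0% in 1 array, replicate 2 of Tsu roots at 24 h without iron, where such a line stays open. The index of that array was 0.838 by the probe sets low in Kas. A mixture would also place many of those near the Kas level, so the share does not tell it from such a line. Shoot tissue is argued against by photosystems genes at no more than 0.974% of their shoots level.

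The third pattern is the set of 357 2-fold rises in Tsu roots at 24 h, among them AT1G10875, AT2G04050 and AT2G21640. Kas material is argued against as their source, since 75.9% lay above all 9 Kas root arrays (60.2% above all 15 other root arrays). A mitochondrial stress response may explain part of them: in a list assembled after the top genes had been seen, AT2G32020 (4.16), AT5G14730 (4.04), AT1G05060 (3.97) and NDB4 (2.69) rose and AT2G41380 had a log2 difference of 0.38. The list's camera adjusted p was 6.94e-12, and 0.0177 with an estimated correlation. Rises of this list were not confined to Tsu: AT1G05060 (2.21) and NDB4 (1.42) also rose in Kas roots at 48 h. There the list did not pass (camera adjusted p = 0.0994), and in Tsu roots at 48 h 0 members passed.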

How the results depend on the processing

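The covariate for the ecotype index, the removal of arrays of intermediate index, the removal of probe sets that differ between ecotypes and the lists by locus alone were tried after the data were seen. No named gene reversed its direction in any alternative. AT3G07720 in Kas roots at 24 h and Tsu roots at 48 h, BHLH101 in Tsu roots at 48 h, and AT1G47400 in Kas shoots at both times and Tsu shoots at 48 h kept their calls without each array in turn. Calls of named genes were lost for 67 of 249 when 1 array was left out. They were lost for 63 of 239 with only the arrays of the groups compared and 18 of 239 with all 36 arrays in 1 fit. The trend and robust options lost 21 of 249, quantile normalization 3 of 249 and the filter on dim probe sets 0 of 174. The index as a covariate lost 24 of 105, and leaving out probe sets that differ between ecotypes lost 2 of 23. Where a count moved, the cause was not tested unless the alternative tests fewer genes or arrays.

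With only the arrays of the groups compared, which leaves fewer arrays for the spread, the counts in roots were 22 (Kas 24 h), 940 (Kas 48 h), 684 (Tsu 24 h), 15 (Tsu 48 h), 1006 (interaction 48 h), 14 (ecotypes) and 1426 (48 h against 24 h). In shoots they were 165 (Tsu 48 h) and 479 (interaction 48 h), shared calls were 2 and 7 in roots at 24 h and 48 h and 25 in shoots at 48 h, and 0 lists passed. With all 36 arrays in 1 fit the counts in roots were 1328, 2908, 3221 and 1349 (Kas 24 h, Kas 48 h, Tsu 24 h, Tsu 48 h), 2615 and 3656 (interactions at 24 h and 48 h), 4289 (ecotypes) and 1574 (48 h against 24 h). In shoots they were 235 and 585 (Kas 24 h and 48 h), 535 (Tsu 48 h), 468 (interaction 48 h) and 637 (48 h against 24 h), and shared calls were 131 and 78 in roots and 31 and 31 in shoots.

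Without dim probe sets, 1178 differed between ecotypes in roots, 107 were shared in shoots at 48 h and 0 lists passed. An estimated correlation left 0 lists, and lists by locus alone gave 9 of 48 tests past the threshold, of which 2 passed with an estimated correlation. Without probe sets that differ between ecotypes, fewer were tested, and the 24 h counts were 93 (Kas roots), 590 (Tsu roots), 452 (interaction in roots), 34 (Kas shoots), 584 (Tsu shoots), 376 (interaction in shoots), 7 (shared in roots) and 3 (shared in shoots). The index as a covariate gave 731 (Kas roots 24 h), 361 (Tsu roots 24 h), 992 (interaction in roots 48 h) and 145 (48 h against 24 h in roots). Without intermediate arrays the counts were 1216 (Kas roots 24 h), 3125 (Tsu roots 48 h), 3494 (interaction in roots 48 h), 4978 (ecotypes in roots) and 84 (shared in roots 48 h). Only Kas replicate 1 (index 1.0) and Tsu replicate 2 (index 0.103) were then left among the root arrays with iron. Each of these counts therefore uses a group of a single array, so its size does not show a cleaner contrast. Quantile normalization moved the share of positive calls from 30.7% to 40.8% for the interaction in roots at 24 h and from 34.7% to 54.8% between ecotypes in roots, where the majority turned. The majority of calls also turned for the interactions in roots and shoots at 48 h (41.9% to 50.6% and 49.4% to 55.7% positive) and for Tsu shoots at 24 h (51.4% to 49.3%). Without dim probe sets it turned for Kas shoots at 48 h and for 48 h against 24 h in shoots. It turned in several alternatives for the interaction in shoots at 48 h and in several arrays left out for tissue by iron, both near even. Quantile normalization shifted the median of all probe sets by at most 0.0635.

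Leaving out each array in turn, the counts ranged in roots from 12 to 1567 (Kas 24 h), 417 to 2276 (Kas 48 h), 495 to 2266 (Tsu 24 h), 55 to 461 (Tsu 48 h), 530 to 2493 and 757 to 2394 (interactions), 460 to 3748 (ecotypes) and 290 to 736 (48 h against 24 h). In shoots they ranged from 161 to 294 (Kas 24 h), 452 to 758 (Kas 48 h), 2641 to 3047 (Tsu 24 h), 360 to 1993 (Tsu 48 h), 2022 to 2425 and 505 to 1577 (interactions), 6257 to 6816 (ecotypes) and 888 to 1596 (48 h against 24 h). Tissue by iron ranged from 868 to 1844, shared calls from 3 to 41 and 15 to 31 in roots and 24 to 57 and 32 to 93 in shoots, and lists from 0 to 2. Arrays that moved a count by over 1.5 times are named with the comparisons. Lists were 0 without Kas roots with iron replicate 1 or 3 or Kas roots at 24 h without iron replicate 1, and 2 without Kas shoots with iron replicate 1.

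Replicate numbers did not pair the samples: 10 of 45 same-number pairs in roots and 1 of 45 in shoots correlated above 0.1, and a block for them lost 0 of 249 named calls and moved no count by over 1.5 times. A pseudocount was not applicable to log2 values. The filter on dim probe sets left 174 of the 249 named calls to test, so it does not show whether signal limits the others.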

Other observations

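Every list test of this part, the splits reported here and the lists for low oxygen and for extensins were chosen after the results had been seen.

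Tsu roots at 48 h raised several genes known from low-oxygen responses, AT3G29970, AT5G66985 and AT3G10040 among them. The other 14 members of a low-oxygen core list had a median log2 change of 1.62 there, with AT3G27220 (2.05), AT5G44730 (2.0) and AT1G19530 (1.45) past the threshold. The camera adjusted p was 6.94e-12, and 0.176 with an estimated correlation, so a low-oxygen response may have occurred but rests on members that move together. At 24 h in Tsu roots the list's median was 1.17 (adjusted p = 8.2e-06, and 0.321 with an estimated correlation), with 5 members past the threshold. AT3G29970, AT5G66985 and AT3G10040 lost their calls without replicate 1 of Tsu roots at 48 h (adjusted p = 0.214, 0.133 and 0.192).

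Extensin-like genes, which build the cell wall of root hairs, were among the largest rises of named genes in Kas roots at 48 h and among the largest falls in Tsu roots. The 6 list members other than the genes that prompted the list had a median of 1.13 in Kas roots at 48 h, with 4 past the threshold. The camera adjusted p was 0.000113, and 0.118 with an estimated correlation. Between these groups the 25S control also went from 10.2 to 6.08 and the index from 0.752 to 0.991. The change in extensins was not separated from either. In Kas roots at 24 h the median was 0.60, with 0 past the threshold (adjusted p = 0.00666, and 0.176 with an estimated correlation). In Tsu roots 2 of the 6 fell at each time, with a median of -0.06 at 24 h (adjusted p = 0.0777) and -0.94 at 48 h (adjusted p = 0.00407, and 0.176 with an estimated correlation). Of 20 gene families tested in 160 tests, 0 passed.

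The iron-deficiency regulators were also tested with members taken by locus code alone, whatever symbol the reference gives. With 10 members the list was past the threshold in Tsu roots at 48 h (adjusted p = 3.5e-05, and 0.0319 with an estimated correlation) and Kas shoots at 48 h (0.000123 and 0.0319), with medians of 0.46 and 0.37. It also passed in Kas roots at 48 h (adjusted p = 0.00252), Kas shoots at 24 h (0.0474) and Tsu shoots at 24 h and 48 h (0.00252 each), and lost these calls with an estimated correlation (0.0730, 0.184, 0.0590 and 0.0590). In Kas and Tsu roots at 24 h it did not pass (0.0911 and 0.280). Iron uptake, with 3 members by locus, passed in Kas roots at 48 h (0.00437) and Tsu roots at 48 h (0.000167), and photosystems fell in Kas roots at 24 h (0.00437), with 0.102, 0.0566 and 0.102 by an estimated correlation.

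For the iron comparisons and the comparisons of ecotypes, 3 arrays against 3 give 10 splits, too few for a share under 0.05. The real split was the highest, 1 of 10, each time. The real and the highest other count were 442 and 210 in Kas roots at 24 h, 1531 and 1 in Kas roots at 48 h, 1587 and 0 in Tsu roots at 24 h, 368 and 44 in Tsu roots at 48 h, and 2243 and 647 between ecotypes in roots. In shoots they were 424 and 0 in Kas at 24 h, 935 and 3 in Kas at 48 h, 3666 and 0 in Tsu at 24 h, 988 and 0 in Tsu at 48 h, and 7549 and 0 between ecotypes. Shared calls as numerous were given by 2 of 100 splits in roots at 24 h (25 real, highest other 51), 1 in roots at 48 h (27, highest other 17), 2 in shoots at 24 h (60, highest other 115) and 1 in shoots at 48 h (65, highest other 1). The highest other counts at 24 h, 51 in roots and 115 in shoots, equal the calls that changed in opposite directions in the ecotypes. Exchanging all iron labels of 1 ecotype gives such a count, since it keeps the calls and reverses their sign. The median of the other splits was 0. The scheme therefore does not test whether sharing exceeds what chance gives for 2 lists of calls. From 24 h to 48 h without iron, 4 of 100 splits gave as many calls in roots (644, highest other 682) and 1 in shoots (1168, highest other 1146). This argues against an arbitrary assignment of the times, though other splits came close to or above the real count. The index of Tsu also went from 0.641 to 0.00754 in roots and from 0.674 to 0.00224 in shoots. A low share therefore does not show an effect of time without iron.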
